A study of Mus musculus with 17 samples.

How the data were processed

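The deposited tables hold expected counts per gene, estimated by the authors with RSEM, which assigns reads to genes and divides reads that match several of them. Per the submitters' processing notes, total RNA was isolated with a Qiagen RNeasy kit, libraries were made with an Illumina kit, and reads were processed with cutadapt 4.8, STAR 2.7.8a and RSEM 1.3.3 on GRCm38, with FastQC 0.11.8 and MultiQC 1.20 for quality. The strand of the libraries and the annotation release are not stated, so reads of overlapping genes on opposite strands are uncertain. Groups were taken from the sample titles, since the treatment label reads Control for all 17 libraries. The labels describe no sorting or purification of the B cells.

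CPM values use the TMM-scaled library total. Those of eGFP, of T cell receptor segments and of Il10 in BMDC, and the folds from counts, use the unscaled total. Each cell type was fitted with its 3 groups in edgeR 4.0.16 (R 4.3.3), with trimmed mean of M-values (TMM) library factors, its default filter on low counts and the quasi-likelihood F test, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The difference between the cell types was tested in 1 fit of all 6 groups. Gene lists (25, fixed with the named-gene rule, the tests and the alternatives before the data were examined) were tested with camera in limma 3.58.1, with the preset correlation of 0.01 and, beside it, an estimated correlation, adjusted over all 150 tests. Named genes were the 6 with the largest fold change in each direction among called genes with a mean of at least 5 CPM, no overlap of CPM between the groups and an established symbol, the key genes, and up to 4 called genes per list with those that went against it. Other genes in the text were chosen after their values were seen. Alternatives were RLE and upper quartile factors, no filter, a stricter filter (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, glmTreat at 1.5-fold, the compared groups alone, the title suffix as a replicate block, and leaving out each library in turn.

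As a self-test, 200 genes per comparison were changed by known amounts in simulated counts. At 1.5, 2 and 4-fold the test recovered 40.3, 68.7 and 89.4% for MSA2 against Control in B cells, 47.8, 65.7 and 87.9% for the combination against Control and 40.3, 65.7 and 89.4% for the combination against MSA2. In BMDC it recovered 65.7, 82.1 and 89.4%, 52.2, 71.6 and 87.9% and 61.2, 86.6 and 93.9% in the same order. Of the calls, 5.71 to 9.62% were unchanged genes. The overlap of opposite changes was set against 20 simulated tables without effects that share the MSA2 libraries. Libraries of B cells with the same title suffix correlated at -0.04 to 0.26 after removal of group means, 3 of 9 pairs above 0.1, all between MSA2 and the combination. The fits, the splits and the simulated tables did not pair by suffix, and a fit with the suffix as a block is among the alternatives. Genes with 0 counts in a group were given a bound from a floor of 3 counts over the group. Read-level data were not used here.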

Results

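RNA sequencing was carried out on 17 mouse libraries, 9 from B cells of the spleen and 8 from bone marrow-derived dendritic cells (BMDC, antigen-presenting cells grown from bone marrow). Per the series description, the cells came from KPC mice, a mouse model of pancreatic cancer, whereas the genotype label reads wild type. The cells were left without drug (Control), incubated with MSA2, an orally available non-nucleotide agonist of the innate immune sensor STING, or incubated with MSA2 and IPI-549 (eganelisib), an inhibitor selective for PI3Kγ, a lipid kinase of white blood cells encoded by Pik3cg. The last group is called the combination here. There were 3 B cell libraries in each group, 3 BMDC libraries in Control and in MSA2, and 2 in the BMDC combination. No group received IPI-549 alone, and the labels give neither dose nor time. Total counts per library ranged from 41093400 to 51433000 in B cells and from 34760000 to 73166600 in BMDC, where MSA2 replicate 2 was the deepest. The labels do not say whether the replicates came from different mice, so the p-values may measure technical spread alone. In B cells 8 of 9 libraries correlated best with a library of their own title suffix, and in BMDC 2 of 8. The main tests did not pair libraries by suffix. By library number, the B cell MSA2 libraries all come after those of Control and the combination, while the BMDC groups are mixed. The labels do not say what this order stands for. A difference in processing therefore cannot be told apart from treatment in the B cell contrasts with MSA2.

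Levels are given as counts-per-million values (CPM), as mean ± SD, and fold changes on the log2 scale with their standard error (SE). Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The key genes, fixed before the data were examined, lie in the GRCm38 build at these positions. They are the cytokine genes Il10 (ENSMUSG00000016529, chromosome 1, 131019845 to 131024974), Ebi3 (ENSMUSG00000003206, chromosome 17, 55952640 to 55957022), Il12a (ENSMUSG00000027776, chromosome 3, 68690644 to 68698547), Ifnb1 (ENSMUSG00000048806, chromosome 4, 88522025 to 88522774), Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007) and Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981). The others are Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), Cd86 (ENSMUSG00000022901, chromosome 16, 36603869 to 36666081), Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), Pik3cg (ENSMUSG00000020573, chromosome 12, 32173473 to 32208659) and Sting1 (ENSMUSG00000024349, chromosome 18, 35733679 to 35740554).

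The first comparison asked what STING activation changed in B cells. With MSA2, genes of the type I interferon response and of inflammatory cytokines rose, and so did genes that mark T cells, NK cells, myeloid cells and red cell precursors. Cxcl10, an interferon-induced chemokine that attracts T cells, rose from 2.03 ± 0.470 to 201 ± 34.9 CPM (n = 3 each), a log2 fold change of 6.63 ± 0.20 SE, adjusted p = 2.51e-09. Il10, the gene of an inhibitory cytokine made by regulatory B cells and by other immune cells, rose from 2.73 ± 0.348 to 14.6 ± 1.26 CPM (2.42 ± 0.39 SE, adjusted p = 0.000468). All 12 B cell marker genes fell, with a median log2 fold change of -0.97. Of 16194 genes tested, 4022 were higher and 2992 lower, 7014 in all, and 2836 passed a test against a minimum change of 1.5-fold.

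Among the interferon-stimulated genes, 25 of 31 measured members rose, 0 fell and 6 had no call (camera adjusted p = 4.62e-09, and adjusted p = 0.0851 with an estimated correlation). The count was the same adjusted over the list alone. Ifit1, an antiviral protein that binds foreign RNA, showed a log2 fold change of 8.39 ± 0.25 SE, adjusted p = 2.51e-09, and Isg15, a ubiquitin-like modifier, one of 4.20 ± 0.19 SE, adjusted p = 2.09e-08. Ifit2 (4.51) and Ifit3b (6.12, whose reads are partly shared with its near copy Ifit3) rose as well. Type I interferon genes themselves appeared. Ifna1 had 2059 counts over the MSA2 libraries and 0 over the Control libraries, at least 755-fold higher against a floor of 3 counts over the group. Ifnb1 had 130 counts against 0, at least 47.7-fold higher. Ifna4 had 1448 counts against 1, a ratio of 1593 with a 95% counting interval of 285 to 62955. Such intervals come from counts pooled over each group and leave out the spread between libraries. Members of the Ifna family share reads, so their single values are uncertain.

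In the cytokine and chemokine list, 17 of 19 measured members rose, 0 fell and 2 had no call, also adjusted over the list alone (camera adjusted p = 1.02e-07, and adjusted p = 0.115 with an estimated correlation). Tnf, a central inflammatory cytokine, rose from 6.59 ± 1.17 to 71.3 ± 15.9 CPM (3.44 ± 0.40 SE, adjusted p = 3.80e-05). Il6, an inflammatory cytokine that acts on B and T cells, showed 4.92 ± 0.33 SE, adjusted p = 3.68e-07. Ccl5 and Il1b, which T cells and myeloid cells make, showed 4.32 ± 0.17 and 4.06 ± 0.23. Of the STING pathway genes, 7 of 16 measured members rose, 0 fell and 9 had no call, and 8 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.0313, and adjusted p = 0.226 with an estimated correlation). The risers included Irf7 (1.29), Trex1 (1.36) and Ikbke (2.21), an interferon regulator, a DNA-degrading enzyme and a kinase, while Sting1 itself showed 0.11 ± 0.09 SE, adjusted p = 0.332. Both groups moved in the libraries in which other-cell markers were high.

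Markers of other blood cells were higher in each MSA2 library of B cells than in every Control and combination library. The 12 T cell markers summed to 1400, 1107 and 1431 CPM with MSA2, against 83.1, 65.3 and 62.8 in Control. All 12 rose, among them Lat (5.57 ± 0.30) and Cd28 (5.93 ± 0.38), parts of T cell signalling. All 10 NK cell markers rose (Nkg7, 6.69 ± 0.41), as did all 15 of monocytes and macrophages (Ccr2, 5.40 ± 0.18), all 12 of neutrophils (Ltf, 7.97 ± 0.52), all 9 of red cell precursors (Hba-a2, 5.54 ± 0.19, which shares reads with Hba-a1) and all 8 of mast cells and basophils. Their median log2 fold changes were 6.33 (T), 6.27 (NK), 5.58 (monocyte), 7.17 (neutrophil), 4.76 (erythroid) and 6.59 (mast cell). With members that had no Control count set to their bound, the neutrophil median was 7.16 and the mast cell median 6.27. Of the dendritic cell markers, 11 of 13 measured members rose, 0 fell and 2 had no call (median 1.66).

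These counts did not change adjusted over each list alone. Camera gave adjusted p = 1.53e-07 for T cell markers (adjusted p = 0.274 with an estimated correlation), adjusted p = 8.28e-07 for NK (adjusted p = 0.250 with an estimated correlation) and adjusted p = 5.91e-12 for monocytes (adjusted p = 0.118 with an estimated correlation). For neutrophils it gave adjusted p = 2.85e-08 (adjusted p = 0.250 with an estimated correlation), for dendritic cells adjusted p = 9.66e-06 (adjusted p = 0.0851 with an estimated correlation), for erythroid cells adjusted p = 6.38e-08 (adjusted p = 0.155 with an estimated correlation) and for mast cells adjusted p = 9.39e-07 (adjusted p = 0.0851 with an estimated correlation). B cell markers moved the other way, adjusted p = 2.56e-08 and adjusted p = 0.115 with an estimated correlation. Ms4a1, which encodes the surface protein CD20, fell from 1453 ± 69.2 to 695 ± 70.9 CPM (-1.06 ± 0.10 SE, adjusted p = 5.84e-06), and Fcer2a and Blnk showed -1.06 ± 0.09 and -0.84 ± 0.07.

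**Figure D1:**
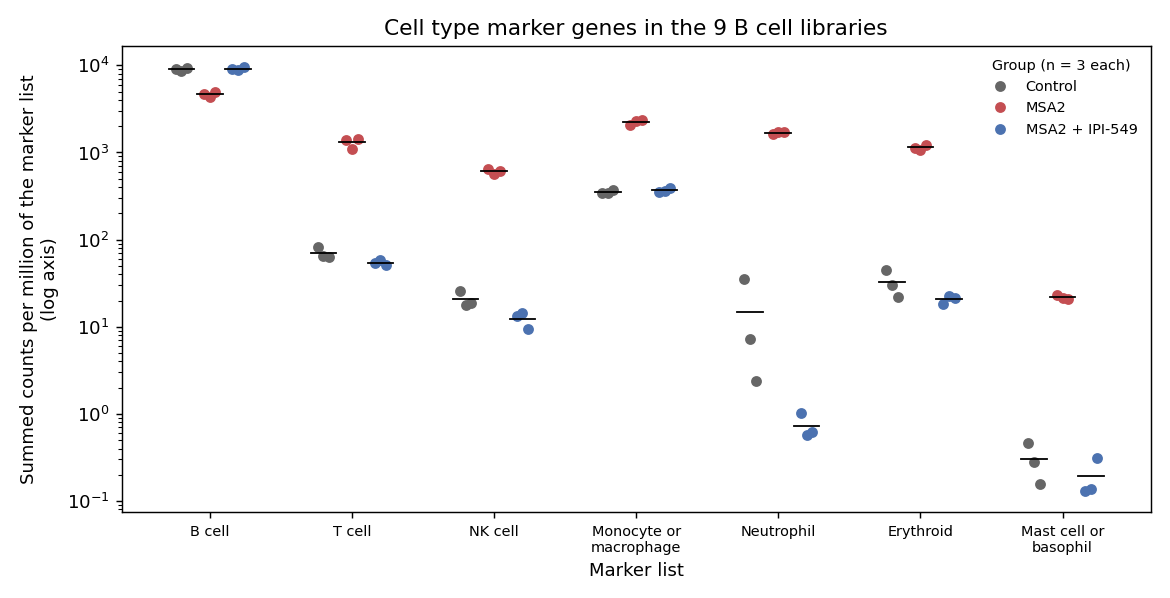
Summed CPM of 7 cell type marker lists (log axis) in the 9 B cell libraries, with 1 point per library, coloured by group, and a black line at each group mean. T cell markers sit between 1107 and 1431 CPM with MSA2 and between 50.6 and 83.1 CPM in the other 6 libraries, and B cell markers sit between 4376 and 4907 with MSA2 and between 8699.5 and 9529.9 in the others.

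In the regulatory B cell list, 12 of 20 measured members rose, 6 fell and 2 had no call, also adjusted over the list alone (camera adjusted p = 0.0343, and adjusted p = 0.309 with an estimated correlation). Besides Il10, strong risers were Ctla4 (3.68), Fasl (6.26) and Gzmb (6.75), an inhibitory receptor, a death ligand and a cytotoxic protease that T cells or NK cells also express. Ebi3, a subunit of the inhibitory cytokine IL-35, showed 0.50 ± 0.13 SE, adjusted p = 0.0108, while Il12a, the gene of its partner subunit, fell from 6.67 ± 1.24 to 3.32 ± 0.670 CPM (-1.01 ± 0.19 SE, adjusted p = 0.00118). Pdcd1lg2, the gene of the checkpoint ligand PD-L2, and Cd24a fell too (-1.14 and -0.73). Cd274, the gene of PD-L1, was at 144 ± 16.8 CPM against 158 ± 16.4 (-0.13 ± 0.10 SE, adjusted p = 0.305). T cell markers rose in the same libraries, and the B cell markers fell by a median of -0.97.

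In the MHC class II list, 0 of 13 measured members rose, 12 fell and 1 had no call (camera adjusted p = 1.18e-07, and adjusted p = 0.236 with an estimated correlation), with H2-DMb2 (-1.22), H2-DMa (-1.08) and H2-Ob (-0.95) among them, all of which act in peptide loading, and the B cell markers fell alongside. In the MHC class I list, 6 of 19 measured members rose, 1 fell and 12 had no call (camera adjusted p = 0.491). Of the costimulation and maturation genes, 8 of 18 measured members rose, 6 fell and 4 had no call, and 8 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.868). Cd86, a ligand that gives T cells a second activating signal, fell from 131 ± 23.3 to 78.1 ± 10.8 CPM (-0.75 ± 0.18 SE, adjusted p = 0.00666), and Cd40 and Icosl fell as well (-0.78 and -0.79). In the same libraries the 12 B cell markers fell by a median of -0.97, more than Cd86, Cd40 or Icosl. The NF-κB target list had 6 members that rose, such as Tnfaip3 (1.65 ± 0.08), which restrains the pathway, 9 that fell, such as Birc3 (-0.65 ± 0.07), and 5 with no call (camera adjusted p = 0.544).

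In the same MSA2 libraries the other-cell markers rose and all 12 B cell markers fell (median -0.97). PI3K genes did not move as a group: 6 of 19 measured members rose, 3 fell and 10 had no call (camera adjusted p = 0.868). Pik3r5, a regulatory subunit of PI3Kγ, rose (1.54 ± 0.07) and Pik3ap1, an adaptor in B cell receptor signalling, fell (-1.05 ± 0.14), whereas Pik3cg showed -0.25 ± 0.11 SE, adjusted p = 0.0979, and 0.0348 without MSA2 replicate 2. In the FOXO target list, 3 of 20 measured members rose, 7 fell and 10 had no call (camera adjusted p = 0.188). Of the MYC and ribosome biogenesis genes, 2 of 20 measured members rose, 12 fell and 6 had no call (camera adjusted p = 0.0197, and adjusted p = 0.334 with an estimated correlation), for example Nhp2 (-0.52). Cholesterol synthesis genes leaned the same way: 1 of 16 measured members rose, 7 fell and 8 had no call (camera adjusted p = 0.0197, and adjusted p = 0.236 with an estimated correlation), with Hmgcs1 at -0.73. Of the glycolysis genes, 8 of 15 measured members rose, 0 fell and 7 had no call (camera adjusted p = 0.0815), led by the lactate transporter Slc16a3 (5.71).

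The other-cell markers, with medians from 4.76 to 7.17, and the B cell markers moved in these libraries too. Cell cycle genes rose in part: 12 of 22 measured members rose, 0 fell and 10 had no call, and 13 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.0306, and adjusted p = 0.740 with an estimated correlation). Mki67, a marker of dividing cells, showed 1.18 ± 0.21. Of the ER and integrated stress genes, 8 of 17 measured members rose, 1 fell and 8 had no call (camera adjusted p = 0.0340, and adjusted p = 0.712 with an estimated correlation). Ppp1r15a, which reverses the stress-induced block of translation, rose from 261 ± 6.80 to 1947 ± 648 CPM. Among the p53 and apoptosis genes, 9 of 18 measured members rose, 4 fell and 5 had no call (camera adjusted p = 0.459), and the cell death genes Pmaip1 and Bbc3 rose (1.57 and 0.92). In the B cell activation and plasmablast list, 6 of 20 measured members rose, 8 fell and 6 had no call, and 7 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.643). Jchain, the joining chain of secreted antibodies, rose (2.22 ± 0.17). Tnfrsf13c, the receptor for the B cell survival factor BAFF, was among the strongest to fall, from 144 ± 19.5 to 38.3 ± 2.59 CPM (-1.91 ± 0.12 SE, adjusted p = 1.92e-07). Medians and means differed in sign, or from the direction camera gave, for the NF-κB, PI3K, FOXO and B cell activation lists.

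The next comparison asked what the combination changed in B cells relative to untreated cells. Of the interferon-stimulated genes 12 of 31 rose and of the cytokine genes 6 of 19, and 171 genes passed in all (111 higher, 60 lower). Cxcl10 reached 84.4 ± 10.1 CPM (5.38 ± 0.20 SE, adjusted p = 6.37e-08, n = 3 each) and Tnf 107 ± 59.0 CPM (4.03 ± 0.41 SE, adjusted p = 0.000342). Il10 was at 3.14 ± 1.94 CPM against 2.73 ± 0.348 in Control (0.20 ± 0.41 SE, adjusted p = 0.918), with 0.903 in combination replicate 3 and 4.29 and 4.24 in the others. No B cell marker passed the test (median log2 fold change 0.01, camera adjusted p = 0.403), and no marker of T cells, NK cells, myeloid cells, red cell precursors or mast cells rose.

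Of the interferon-stimulated genes, 12 of 31 measured members rose, 0 fell and 19 had no call, and 13 rose and 0 fell adjusted over the list alone (camera adjusted p = 2.13e-20, and adjusted p = 0.0531 with an estimated correlation). Ifit1 showed 8.37 ± 0.25 SE, adjusted p = 1.74e-08, Isg15 4.08 ± 0.19 SE, adjusted p = 3.35e-07 and Ifit2 5.45 ± 0.15. Ifna1 had 5128 counts against 0 in Control, at least 1746-fold higher, Ifnb1 137 counts against 0, at least 46.7-fold higher (adjusted p = 0.0114), and Ifna4 3917 counts against 1, a ratio of 4002 (718 to 158106). In the cytokine list, 6 of 19 measured members rose, 1 fell and 12 had no call, and 6 rose and 2 fell adjusted over the list alone (camera adjusted p = 2.56e-08, and adjusted p = 0.108 with an estimated correlation). Il6 rose (3.88 ± 0.33 SE, adjusted p = 8.11e-05), as did Ccl4, a chemokine for T cells and monocytes (3.36 ± 0.18). Tnf was uneven between the combination libraries, at 118, 160.3 and 43.8 CPM.

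The regulatory B cell list had 0 calls among 20 measured members, and 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.359). Cd274 stood at 218 ± 1.97 CPM against 158 ± 16.4 (0.46 ± 0.10 SE, adjusted p = 0.0568), and at adjusted p = 0.0345 without Control replicate 3. Cd86 showed -0.14 ± 0.18 SE, adjusted p = 0.858 and Pik3cg -0.13 ± 0.11 SE, adjusted p = 0.775. NF-κB targets included 2 risers among 20, Nfkbiz (1.73 ± 0.08) and Tnfaip3 (1.44 ± 0.08), or 3 adjusted over the list alone (camera adjusted p = 0.00961, and adjusted p = 0.131 with an estimated correlation). The STING pathway list had 2 as well, Trex1 (1.67 ± 0.16) and Irf7 (1.10 ± 0.12), with camera adjusted p = 0.344. The costimulation list had 1, Marcksl1 (1.03 ± 0.12), or 2 adjusted over the list alone (camera adjusted p = 0.0454, and adjusted p = 0.226 with an estimated correlation). Of 17 ER and integrated stress genes 2 rose, Ppp1r15a (3.22 ± 0.24) and Atf3 (1.36 ± 0.14), and 15 had no call (camera adjusted p = 0.000913, and adjusted p = 0.548 with an estimated correlation). Of 18 p53 and apoptosis genes 2 rose, Pmaip1 (2.62 ± 0.10) and Bbc3 (2.14 ± 0.11), and 16 had no call, while 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0476, and adjusted p = 0.432 with an estimated correlation).

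No member of the PI3K, MHC class I, MHC class II, MYC, glycolysis, cholesterol, cell cycle or B cell activation lists passed by edgeR over all genes, with camera adjusted p-values between 0.116 and 0.973. Socs3, an inhibitor of cytokine signalling, fell (-1.52 ± 0.11 SE, adjusted p = 2.74e-05), as did the oxidative stress gene Osgin1 (-2.09 ± 0.24 SE, adjusted p = 0.000745). Among T cell markers 1 of 12 fell, and 10 did adjusted over the list alone (median -3.25, camera adjusted p = 3.09e-09, and adjusted p = 0.226 with an estimated correlation). Of the neutrophil markers 0 passed over all genes and 7 fell adjusted over the list alone (median -3.80, camera adjusted p = 2.70e-06, and adjusted p = 0.303 with an estimated correlation). The Control libraries were uneven here, with neutrophil marker sums of 35.3, 7.19 and 2.38 CPM in replicates 1, 2 and 3. NK cell markers had 0 calls and 5 adjusted over the list alone (camera adjusted p = 0.000532, and adjusted p = 0.367 with an estimated correlation), and of those of monocytes and macrophages 1 fell (camera adjusted p = 0.0448, and adjusted p = 0.591 with an estimated correlation). In the erythroid list 2 fell, Slc4a1 (-1.24 ± 0.14) and Hba-a2 (-0.92 ± 0.19), camera adjusted p = 0.000206, and adjusted p = 0.286 with an estimated correlation. The Hba-a2 call was lost without any 1 library other than Control replicate 3, with adjusted p from 0.0840 to 0.208.

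Without Control replicate 2 the combination changed 91 genes and without combination replicate 1 it changed 112, while DESeq2 called 385 and a test against a minimum of 1.5-fold 64. A fit without the MSA2 libraries called 212. The lean to higher was not firm, with 193 higher and 192 lower by DESeq2, 187 and 172 without a filter, 88 and 81 without Control replicate 3, and 594 and 970 at an unadjusted p under 0.05.

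The question of adding IPI-549 was addressed in B cells by the combination against MSA2 alone. Il10 was lower in the combination, at 3.14 ± 1.94 against 14.6 ± 1.26 CPM (-2.21 ± 0.39 SE, adjusted p = 0.000869, n = 3 each). Cd274 was higher, at 218 ± 1.97 against 144 ± 16.8 CPM (0.59 ± 0.10 SE, adjusted p = 0.000543). All 12 B cell markers were higher (median log2 fold change 0.93), and all markers of T cells, NK cells, monocytes and macrophages, neutrophils, red cell precursors and mast cells were lower. In total 5983 genes passed, 2279 higher and 3704 lower, and 2614 of the genes passed against a minimum change of 1.5-fold.

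T cell markers showed the difference in counts. Cd3e, part of the T cell receptor complex, had 0 counts in the combination and 7914 with MSA2, at least 2840.3-fold lower, and Bcl11b, a T cell transcription factor, was at least 3619.8-fold lower. The neutrophil granule gene Cd177 was at least 1685-fold lower. Camera gave adjusted p = 4.18e-09 for T cell markers (adjusted p = 0.226 with an estimated correlation), adjusted p = 8.91e-08 for NK (adjusted p = 0.226 with an estimated correlation), adjusted p = 1.18e-12 for monocytes (adjusted p = 0.115 with an estimated correlation) and adjusted p = 9.99e-10 for neutrophils (adjusted p = 0.226 with an estimated correlation). It gave adjusted p = 1.93e-06 for dendritic cells (adjusted p = 0.0851 with an estimated correlation), adjusted p = 1.17e-08 for erythroid cells (adjusted p = 0.131 with an estimated correlation), adjusted p = 3.35e-07 for mast cells (adjusted p = 0.0851 with an estimated correlation) and adjusted p = 3.75e-09 for B cell markers (adjusted p = 0.108 with an estimated correlation). Of 13 dendritic cell markers 10 fell, or all 13 adjusted over the list alone.

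In the regulatory B cell list, 5 of 20 measured members rose, 12 fell and 3 had no call, and 6 rose and 12 fell adjusted over the list alone (camera adjusted p = 0.0405, and adjusted p = 0.319 with an estimated correlation). Lower were Ctla4 (-3.93), Cd5 (-5.67) and Fasl (-7.61), as T cell markers were, and higher were Cd24a (0.82), Tgfb1 (0.43) and Cd274 (0.59). Gzmb had 2 counts against 5530 with MSA2. Ebi3 showed -0.38 ± 0.13 SE, adjusted p = 0.0453, a call lost on leaving out any 1 library of the pair (adjusted p from 0.0586 to 0.124). Il12a showed 0.52 ± 0.19 SE, adjusted p = 0.0510, and passed without MSA2 replicate 1 (0.0371) or combination replicate 3 (0.0344). Its adjusted p was 0.0153 with the title suffix as a block, the lowest of a range that reached 1 over the alternatives. In the MHC class II list, 12 of 13 measured members rose, 0 fell and 1 had no call (camera adjusted p = 6.76e-08, and adjusted p = 0.234 with an estimated correlation), alongside the B cell markers.

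Interferon-stimulated genes differed in both directions: 2 of 31 measured members rose, 14 fell and 15 had no call (camera adjusted p = 0.117), and 3 rose and 14 fell adjusted over the list alone. Oas3 and Ifih1, antiviral sensors, were lower (-2.16 ± 0.12 and -1.58 ± 0.20), Ifit2 and Oasl1 higher (0.94 ± 0.12 and 1.10 ± 0.17), and Isg15 showed -0.12 ± 0.16 SE, adjusted p = 0.596. In the cytokine list, 2 of 19 measured members rose, 11 fell and 6 had no call, and 2 rose and 12 fell adjusted over the list alone (camera adjusted p = 0.00716, and adjusted p = 0.303 with an estimated correlation). Cxcl10 and Il6 were lower (-1.25 ± 0.15 and -1.03 ± 0.24), and so were Ccl5 and Il1b (-4.10 ± 0.17 and -5.16 ± 0.25), in which the T cell and myeloid markers moved alike. Tnf showed 0.59 ± 0.36 SE, adjusted p = 0.221, and 0.00258 without combination replicate 3. Ifnb1 showed 0.08 ± 0.51 SE, adjusted p = 0.913.

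Cd86 was higher, at 119 ± 29.1 against 78.1 ± 10.8 CPM (0.60 ± 0.18 SE, adjusted p = 0.0234), a call lost without MSA2 replicate 3 (0.0647), combination replicate 1 (0.0731) or combination replicate 2 (0.0964). Pik3cg showed 0.12 ± 0.11 SE, adjusted p = 0.435, while of the PI3K genes 4 were higher, including Pik3ap1 (0.92 ± 0.14), and 6 lower, including Pik3r5 (-1.50 ± 0.07), with camera adjusted p = 0.966. In the FOXO target list, 8 of 20 measured members rose, 1 fell and 11 had no call (camera adjusted p = 0.0827), with Foxo1 and Bcl6 higher (0.55 ± 0.08 and 0.51 ± 0.09). Among cell cycle genes, 0 of 22 measured members rose, 13 fell and 9 had no call, and 0 rose and 14 fell adjusted over the list alone (camera adjusted p = 0.0154, and adjusted p = 0.714 with an estimated correlation). Of the MYC and ribosome genes, 6 of 20 measured members rose, 0 fell and 14 had no call (camera adjusted p = 0.0306, and adjusted p = 0.367 with an estimated correlation), or 5 adjusted over the list alone. Pmaip1 and Bbc3 were higher in the combination (1.05 ± 0.09 and 1.21 ± 0.11), and Tnfrsf13c, the BAFF receptor gene, was higher too (1.39 ± 0.11). In the same contrast the other-cell markers were lower and the B cell markers higher (median 0.93).

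Of the genes that MSA2 raised in B cells, 3420 were lower in the combination, against 919.9 for independent lists, and of those it lowered 1878 were higher, against 421, so 5298 moved back and 34 moved further the same way. Both comparisons use the MSA2 libraries, which adds to such counts. These alone held T cell markers at 1107 to 1431 CPM, so genes of other cells are among those raised and then lower. Simulated tables with no effect gave at most 1 gene with opposite calls. Between the log2 fold changes across genes, which are not independent replicates, they gave a correlation of -0.49 and a covariance of -0.04. The data gave -0.93 and -2.56. The simulated tables hold no effect at all, whereas a trait of the MSA2 libraries alone would move both comparisons in opposite ways. Neither they nor independent lists can therefore tell such a trait from an effect of IPI-549.

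In BMDC, the comparison of MSA2 with Control asked what STING activation changed in dendritic cells. Type I interferon, inflammatory cytokine and costimulation genes rose. Ifnb1, the gene of interferon beta, rose from 3.75 ± 6.44 to 1025 ± 66.9 CPM (7.99 ± 0.96 SE, adjusted p = 9.82e-05, n = 3 each). Control replicate 2 set the Control mean of Ifnb1 (0, 11.2 and 0.0577 CPM in replicates 1, 2 and 3). Tnf rose from 16.0 ± 11.3 to 1872 ± 368 CPM (6.85 ± 0.46 SE, adjusted p = 1.23e-06, and a log2 fold change of 7.56 without Control replicate 2). Cd86 rose from 107 ± 1.43 to 218 ± 13.6 CPM (1.03 ± 0.06 SE, adjusted p = 5.48e-07) and Cd274 from 254 ± 16.3 to 538 ± 45.7 CPM (1.08 ± 0.08 SE, adjusted p = 2.12e-06). Of 14613 genes tested 4118 passed, 2140 higher and 1978 lower, and 772 passed against a minimum change of 1.5-fold.

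Of the interferon-stimulated genes, 26 of 31 measured members rose, 0 fell and 5 had no call, also adjusted over the list alone (camera adjusted p = 4.05e-16, and adjusted p = 0.226 with an estimated correlation). Isg15 rose from 10.2 ± 5.09 to 661 ± 128 CPM, Rsad2, the antiviral protein viperin, showed 6.03 ± 0.27, and Mx2 5.68 ± 0.27. In the cytokine and chemokine list, 22 of 23 measured members rose, 0 fell and 1 had no call, also adjusted over the list alone (camera adjusted p = 3.16e-16, and adjusted p = 0.0851 with an estimated correlation). Cxcl10 reached 1676 ± 216 CPM from 7.45 ± 9.78 (7.76 ± 0.76 SE, adjusted p = 2.06e-05, and a log2 fold change of 9.86 without Control replicate 2), Il6 reached 138 ± 22.9 CPM from 1.01 ± 0.859 (adjusted p = 4.37e-08, and a log2 fold change of 8.06 without Control replicate 2) and Il12b, a subunit of the T cell-polarising cytokine IL-12, 5.72 ± 0.24. Il12a, the other subunit, showed 1.07 ± 0.30 SE, adjusted p = 0.0207, a call lost without Control replicate 1 (0.0517), Control replicate 3 (0.0670), MSA2 replicate 2 (0.0546) or MSA2 replicate 3 (0.0711). Il10 was at or below 0.183 CPM in every BMDC library and was not tested.

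NF-κB targets rose: 17 of 20 measured members rose, 0 fell and 3 had no call, and 17 rose and 1 fell adjusted over the list alone (camera adjusted p = 7.29e-11, and adjusted p = 0.0851 with an estimated correlation). Tnfaip3 and Nfkbia, which restrain NF-κB, showed 4.21 ± 0.16 and 2.59 ± 0.09. Of the costimulation and maturation genes, 16 of 20 measured members rose, 1 fell and 3 had no call, also adjusted over the list alone (camera adjusted p = 9.99e-10, and adjusted p = 0.131 with an estimated correlation). Cd40 and Tnfsf9, which engage T cells, rose (2.28 ± 0.08 and 3.41 ± 0.13), and Icosl, the ligand of the T cell receptor ICOS, fell (-1.54 ± 0.11). In the MHC class I list, 10 of 19 measured members rose, 0 fell and 9 had no call (camera adjusted p = 0.00273, and adjusted p = 0.566 with an estimated correlation), among them the peptide-loading gene Tapbp (0.59 ± 0.08). In the MHC class II list, 0 of 13 measured members rose, 3 fell and 10 had no call (camera adjusted p = 0.812), and 0 rose and 2 fell adjusted over the list alone.

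In the STING pathway list, 8 of 16 measured members rose, 2 fell and 6 had no call, and 8 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.152). Trex1 rose (2.72 ± 0.19). Nlrc3, a negative regulator of STING, fell (-0.92 ± 0.17), and Sting1 showed -0.13 ± 0.06 SE, adjusted p = 0.136. Pik3cg fell from 209 ± 23.5 to 171 ± 2.86 CPM (-0.29 ± 0.08 SE, adjusted p = 0.0176, and 0.0829 without Control replicate 1). Among the PI3K genes 4 of 19 measured members rose, 3 fell and 12 had no call (camera adjusted p = 0.860), and with upper quartile scaling 3 rose and 6 fell. In the FOXO target list, 2 of 19 measured members rose, 8 fell and 9 had no call (camera adjusted p = 0.0820), and Tsc22d3 and Sesn1 showed -2.22 ± 0.15 and -1.08 ± 0.12. Cell cycle genes rose in part: 11 of 22 measured members rose, 0 fell and 11 had no call, and 12 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.000239, and adjusted p = 0.303 with an estimated correlation). Among p53 and apoptosis genes, 5 of 19 measured members rose, 3 fell and 11 had no call (camera adjusted p = 0.0846), with Pmaip1 at 3.17 ± 0.16 and Bbc3 at 1.92 ± 0.09.

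Of the genes with the largest falls, Id3, an inhibitor of E-protein transcription factors, showed -3.82 ± 0.29 SE, adjusted p = 3.41e-06, Trib1 -2.89 ± 0.38 and Klf10 -2.56 ± 0.13. In the dendritic cell marker list, 2 of 12 measured members rose, 3 fell and 7 had no call. Xcr1, a chemokine receptor of cross-presenting dendritic cells, rose (4.20 ± 0.26) and Itgax, the gene of CD11c, fell (-0.43 ± 0.07). The B cell marker list had 2 of 6 measured members that fell, or 4 adjusted over the list alone (camera adjusted p = 0.0232, and adjusted p = 0.301 with an estimated correlation). Other marker lists gave camera adjusted p-values from 0.0631 to 0.795. Control replicate 2 held more interferon and cytokine RNA than the other Control libraries, with Ifnb1 at 11.2 CPM and Cxcl10 at 18.7 CPM. Upper quartile factors called 4574 genes, 36.7% of them higher, against 52.0% of the 4118.

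The combination was then set against Control in BMDC, with 2 combination libraries and 3 Control libraries. Interferon, cytokine and costimulation genes rose here too, against the same Control libraries, of which replicate 2 held more interferon and cytokine RNA. Ifnb1 reached 654 ± 28.8 CPM (7.34 ± 0.96 SE, adjusted p = 0.000379), against a Control mean that rests on replicate 2 (0, 11.2 and 0.0577 CPM), Tnf 1329 ± 176 CPM (6.36 ± 0.46 SE, adjusted p = 3.82e-06, and 7.07 without Control replicate 2) and Cd86 177 ± 10.3 CPM (0.74 ± 0.07 SE, adjusted p = 3.26e-05). Cd274 showed 1.05 ± 0.09 SE, adjusted p = 9.78e-06, and Pik3cg -0.28 ± 0.09 SE, adjusted p = 0.0603 (0.0132 without Control replicate 2). Of the 14613 genes, 1097 were higher and 786 lower.

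Of the interferon-stimulated genes, 22 of 31 measured members rose, 0 fell and 9 had no call, and 23 rose and 0 fell adjusted over the list alone (camera adjusted p = 4.55e-15, and adjusted p = 0.226 with an estimated correlation). Isg15 showed 5.72 ± 0.30 SE, adjusted p = 3.21e-07 and Rsad2 4.85 ± 0.26. In the cytokine list, 21 of 23 measured members rose, 0 fell and 2 had no call, and 22 rose and 0 fell adjusted over the list alone (camera adjusted p = 9.72e-18, and adjusted p = 0.0851 with an estimated correlation). Cxcl10 showed 7.02 ± 0.75 SE, adjusted p = 8.89e-05, Il6 6.09 ± 0.32 SE, adjusted p = 3.19e-07 (without Control replicate 2, 9.12 and 7.15) and Il12b 5.43 ± 0.24. NF-κB targets rose as well: 17 of 20 measured members rose, 0 fell and 3 had no call (camera adjusted p = 2.43e-12, and adjusted p = 0.0851 with an estimated correlation), with Tnfaip3 at 3.66 ± 0.16. In the costimulation list, 16 of 20 measured members rose, 1 fell and 3 had no call (camera adjusted p = 7.29e-11, and adjusted p = 0.118 with an estimated correlation), with Cd40 at 1.90 ± 0.08 and Icosl at -1.43 ± 0.13. MHC class I genes rose in part: 9 of 19 measured members rose, 0 fell and 10 had no call, and 11 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.000114, and adjusted p = 0.445 with an estimated correlation). Of the cell cycle genes, 5 of 22 measured members rose, 0 fell and 17 had no call, and 7 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.000338, and adjusted p = 0.307 with an estimated correlation).

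Id3 and Trib1 fell (-2.98 ± 0.33 and -3.19 ± 0.47), as did Osgin1 (-2.42 ± 0.23) and Dusp5, a phosphatase that switches off ERK (-2.20 ± 0.21). Without combination replicate 1 the count of 1883 calls was 843 and without combination replicate 2 it was 1036, with the remaining library assumed to vary like the other groups. A test against 1.5-fold gave 427, and upper quartile factors called 1984 genes, 47.3% of them higher, against 58.3% of the 1883.

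When IPI-549 was added to MSA2 in BMDC, 0 genes passed an adjusted p of 0.05 by edgeR's quasi-likelihood test (2 against 3 libraries, smallest adjusted p 0.0687). At an unadjusted p under 0.05 there were 1595 genes, 664 higher and 931 lower, while DESeq2 called 154 and limma-voom 3 (Il1a, Rgs2 and Gm49519, named after their values were seen). Most interferon and cytokine genes had negative values. The interferon-stimulated list had a median log2 fold change of -0.44, with 0 of 31 members called over all genes and 17 lower adjusted over the list alone (camera adjusted p = 2.29e-10, and adjusted p = 0.301 with an estimated correlation). The cytokine list had a median of -0.70, with 0 of 23 called and 9 lower adjusted over the list alone (camera adjusted p = 2.93e-06, and adjusted p = 0.226 with an estimated correlation).

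Among single genes, Il1a, an inflammatory cytokine, showed -1.04 ± 0.13 SE, adjusted p = 0.0687 over all genes and 0.000218 adjusted over the list alone. Rsad2 showed -1.18 ± 0.25 SE, adjusted p = 0.174 over all genes and 0.00549 adjusted over the list alone. Il6 was at 73.6 ± 4.38 CPM in the combination against 138 ± 22.9 with MSA2 (-0.91 ± 0.23 SE, adjusted p = 0.243), Cd86 at 177 ± 10.3 against 218 ± 13.6 CPM (-0.30 ± 0.07 SE, adjusted p = 0.220) and Ifnb1 at 654 ± 28.8 against 1025 ± 66.9 CPM (-0.65 ± 0.77 SE, adjusted p = 0.812). Cd274 showed -0.03 ± 0.09 SE, adjusted p = 0.935 and Pik3cg 0.01 ± 0.09 SE, adjusted p = 0.990. The costimulation list had 0 of 20 called and 5 lower adjusted over the list alone, including Cd40 and Cd80 (camera adjusted p = 0.000326, and adjusted p = 0.301 with an estimated correlation), and the NF-κB list 0 of 20 and 2 (camera adjusted p = 0.00219, and adjusted p = 0.282 with an estimated correlation). FOXO targets leaned upward, with 0 of 19 called and 3 higher adjusted over the list alone (camera adjusted p = 0.0184, and adjusted p = 0.566 with an estimated correlation), and glycolysis genes with 0 of 15 by either (camera adjusted p = 0.0197, and adjusted p = 0.591 with an estimated correlation). The 6 measured B cell markers leaned upward with 0 calls (camera adjusted p = 0.0476, and adjusted p = 0.326 with an estimated correlation).

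Leaving out MSA2 replicate 2, the deepest library, gave 99 calls (16 higher, 83 lower), without MSA2 replicate 1 there were 6, and without MSA2 replicate 3 there was 1, Il1a. With no filter on low counts 561 genes passed, with the compared groups alone 13, and no gene that MSA2 had changed passed in the opposite direction (96 without MSA2 replicate 2).

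Whether the MSA2 effect differed between the cell types was tested as the BMDC log2 fold change minus that of B cells, in a fit of all 17 libraries. B cell and BMDC libraries were numbered in separate series, and the labels give neither dose nor time. The test compares effects within each series, so a difference of batch or exposure cannot be told apart from one of cell type. Tnf rose more in BMDC than in B cells (difference 3.43 ± 0.61 SE, adjusted p = 0.000205), as did Isg15 (1.80 ± 0.34 SE, adjusted p = 0.000369). BMDC Control replicate 2 held more RNA of both genes than the other Control libraries (Tnf 28.4 CPM, against 6.24 and 13.5). This makes their BMDC fold changes smaller. Cd274 and Cd86 rose in BMDC, while Cd86 fell in B cells, and the differences were 1.22 ± 0.14 SE, adjusted p = 1.29e-06, for Cd274 and 1.79 ± 0.20 SE, adjusted p = 1.43e-06, for Cd86. Il12a, which rose in BMDC (a call lost without Control replicate 1, Control replicate 3, MSA2 replicate 2 or MSA2 replicate 3, at 0.0517 to 0.0711) and fell in B cells, differed by 2.08 ± 0.33 SE, adjusted p = 6.42e-05. In the B cell MSA2 libraries the 12 B cell markers fell by a median of -0.97, against -0.75 for Cd86, -1.01 for Il12a and -0.13 for Cd274. A fall of Cd86 or Il12a within B cells cannot be told apart from a smaller share of B cell RNA. Of 17739 genes tested, 6558 differed, 2888 with the higher log2 fold change in BMDC and 3670 with the higher in B cells, where the other-cell markers had risen, and 2918 passed against 1.5-fold.

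The differences of Cxcl10 (1.15 ± 0.78 SE, adjusted p = 0.278), Il6 (2.10 ± 0.82 SE, adjusted p = 0.0540) and Pik3cg (-0.03 ± 0.14 SE, adjusted p = 0.918) did not pass. Without BMDC Control replicate 2 those of Cxcl10 (3.24, adjusted p = 8.91e-08) and Il6 (3.15, adjusted p = 0.000666) did. For the addition of IPI-549 to MSA2, Cd86 and Cd274 differed between the cell types (-0.94 ± 0.22 SE, adjusted p = 0.00336, and -0.66 ± 0.15 SE, adjusted p = 0.00238), as both were higher in B cells and neither passed in BMDC. In that B cell contrast the 12 B cell markers were higher by a median of 0.93, more than Cd86 or Cd274, and the other-cell markers were lower. In all, 4274 genes differed in that contrast, 2708 with the higher value in BMDC and 1566 with the higher in B cells, and 2002 passed against 1.5-fold. The difference of Tnf was -1.12 ± 0.60 SE, adjusted p = 0.208, and -1.49, adjusted p = 0.0434, without B cell combination replicate 3.

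**Figure D2:**
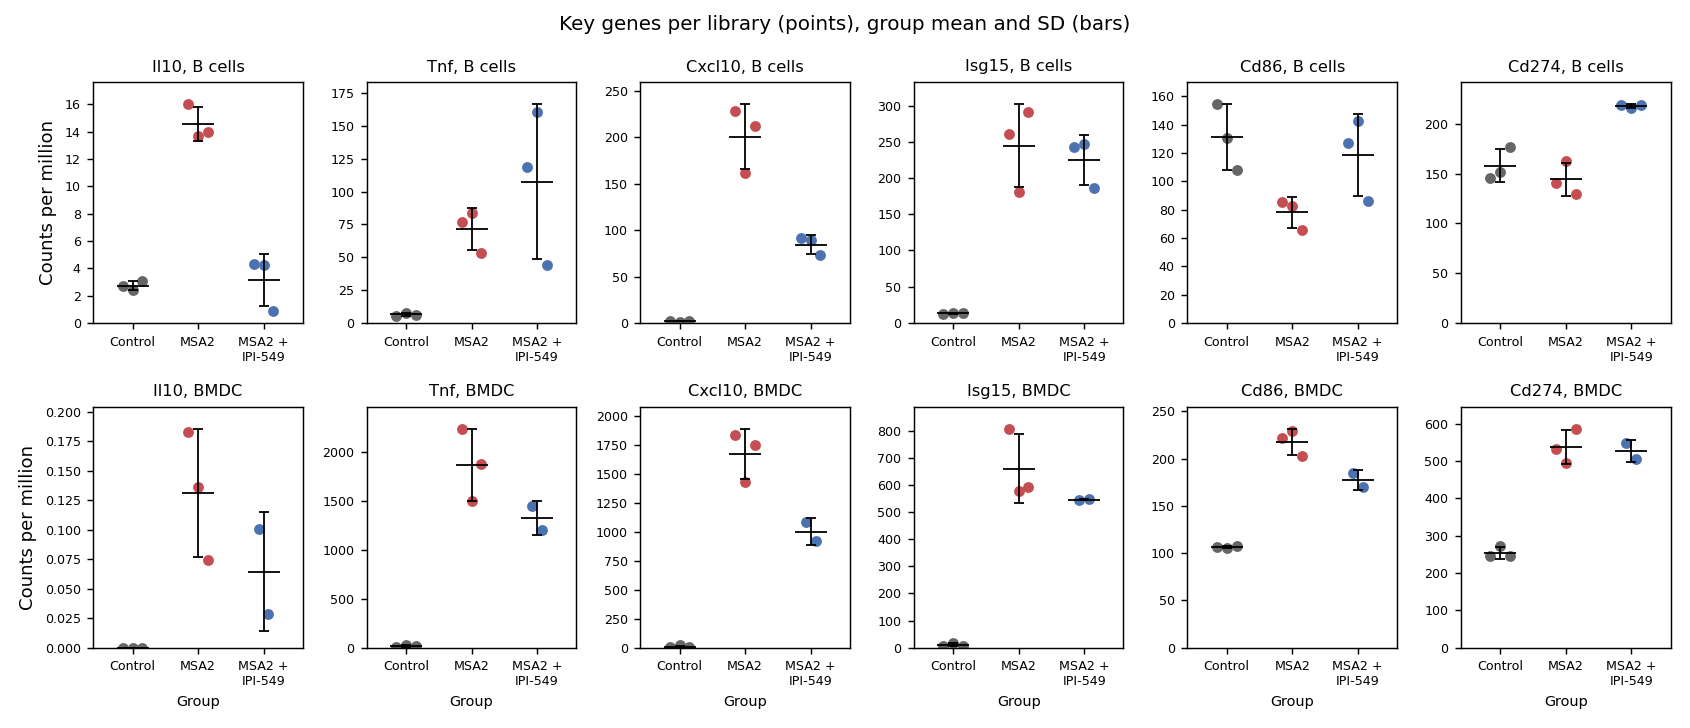
Levels in CPM of Il10, Tnf, Cxcl10, Isg15, Cd86 and Cd274 in B cells (top) and BMDC (bottom), with 1 point per library and bars for the group mean and SD (n = 3, and n = 2 in the BMDC combination). Il10 in B cells averaged 14.6 CPM with MSA2 and 3.14 CPM in the combination, and Cd86 averaged 78.1 CPM with MSA2 in B cells and 218 CPM with MSA2 in BMDC.

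**Figure D3:**
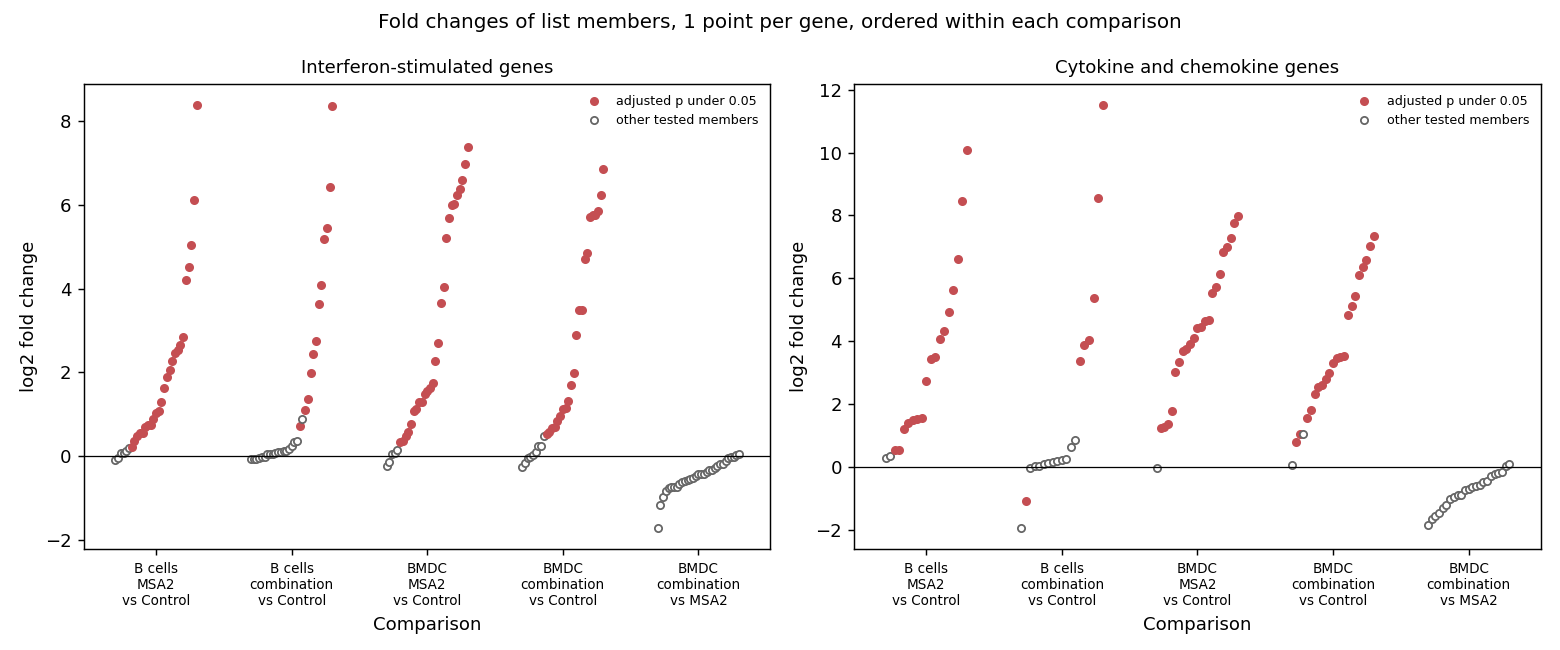
Log2 fold changes of the members of the interferon-stimulated list (left) and the cytokine and chemokine list (right) in 5 comparisons, with 1 point per gene, filled where the adjusted p was under 0.05 (fitted values of genes at 0 in Control are no bound). In BMDC 26 and 22 members rose with MSA2, and the combination against MSA2 had medians of -0.44 and -0.70 with 0 calls by edgeR.

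Across the 25 lists and 6 comparisons, camera with its preset correlation called 61 of 150 tests at an adjusted p under 0.05. With an estimated correlation 0 held, and the smallest adjusted p was 0.0531. That correlation is estimated from few libraries. Even the T cell markers in B cells with MSA2, of which 12 of 12 rose (median 6.33), gave camera adjusted p = 0.274 there. A list that did not hold is thus not shown to be unmoved. Outside the first comparison, median, mean and test differed in sign for uncalled lists alone, such as the PI3K list in the combination against MSA2 in both cell types.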

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

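The tests of other spleen cells, of normalization, of the source of Il10 and both tests of BMDC Control replicate 2 were chosen after the result was seen, and the T cell receptor test and the other splits of the libraries were written before. 7 differences were picked out because the effect differed between BMDC and B cells in a test of the difference itself (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With MSA2 against Control these were Cd274 (1.22 ± 0.14 SE, adjusted p = 1.29e-06), Cd86 (1.79 ± 0.20 SE, adjusted p = 1.43e-06), Tnf (3.43 ± 0.61 SE, adjusted p = 0.000205), Il12a (2.08 ± 0.33 SE, adjusted p = 6.42e-05) and Isg15 (1.80 ± 0.34 SE, adjusted p = 0.000369). With the combination against MSA2 they were Cd274 (-0.66 ± 0.15 SE, adjusted p = 0.00238) and Cd86 (-0.94 ± 0.22 SE, adjusted p = 0.00336). In B cells the 12 B cell markers moved by medians of -0.97 and 0.93 in these contrasts, and the other-cell markers moved the opposite way. The cell types were also in separate library series. A difference in response therefore cannot be told apart here from one in library make-up or batch. BMDC Control replicate 2 held more Tnf and Isg15 RNA than the other Control libraries.

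T cell, NK cell, myeloid, red cell precursor and mast cell genes were high in all 3 MSA2 libraries of B cells. Normalization factors are argued against, since the smallest median log2 fold change of these 6 lists was 4.74 with RLE or upper quartile factors. Transcription of T cell genes by the B cells themselves is argued against by T cell receptor beta variable segments, which are joined in T cells. They summed in the lowest MSA2 library to 39.6 times the highest Control library. In each MSA2 library 20 of 35 segments had at least 10 counts, against 1, 0 and 0 segments in Control replicates 1, 2 and 3. Gene counts do not show whether the segments were joined. They also do not cover the NK cell, myeloid, red cell precursor or mast cell genes, for which this explanation was not tested. Other spleen cells in the MSA2 libraries remain a candidate explanation, with the B cell markers at a median of -0.97. A biological shift in which cells survived MSA2 stays open and untested. The combination libraries received MSA2 too and held 1, 0 and 0 counts of these segments, but they also received IPI-549. Whether the 3 MSA2 libraries carry another sample's label was not tested either. Their library numbers all follow those of Control and the combination, so a difference in processing cannot be told apart from MSA2.

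Il10 was higher in the same MSA2 libraries. The reads may come from the other cells or from B cells that responded to MSA2. In the combination, where no other-cell marker rose against Control, the log2 fold change of Il10 against Control was 0.20. This value leans on combination replicate 3, at 0.903 CPM. Replicates 1 and 2, at 4.29 and 4.24 CPM, lay above the Control range of 2.38 to 3.08 CPM. IPI-549 was present in the same libraries, so even a missing rise would have 2 readings and these explanations cannot be told apart.

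BMDC Control replicate 2 held more Ifnb1 and Cxcl10 RNA than the other Control libraries. Reads or RNA carried over from a treated library, or weak activation of that culture, could give this. Carry-over needs 1 fixed share of the MSA2 level for every strongly induced gene, and between 61.5% and 100% of such genes lay within 1.5 times the median share, depending on which of 4 cut-offs defined strong induction. The cut-offs were not fixed beforehand and several were tried, so the explanations cannot be told apart.

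In each 3 against 3 comparison 10 splits of the libraries exist, too few for a share under 0.05. The real split was the 1 with as many calls in B cells for MSA2 against Control (7014, highest other 0), the combination against Control (171, highest other 1) and the combination against MSA2 (5983, highest other 0), and in BMDC for MSA2 against Control (4118, highest other 0). For the difference between the cell types, 1 of 50 splits drawn from 200 gave as many calls, the real one with 6558, and the highest other, which kept the groups of both cell types with those of BMDC mirrored, gave 5996.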

How the results depend on the processing

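All alternatives were planned, but the Trim and Tlr families below were chosen after their values were seen. No single named gene called in the main fit or in the alternative changed its sign. Sign changes of genes called in neither were not counted. Upper quartile factors turned the majority of BMDC calls from higher to lower (MSA2 against Control 1678 higher and 2896 lower, the combination against Control 938 and 1046). In BMDC they also turned that of the PI3K list (3 higher, 6 lower), the glycolysis list (3 and 5) and the Trim genes (8 and 10) with MSA2. With the combination against Control they turned that of the Tlr genes (2 and 3). Calls of single named genes were lost in 207 comparisons against 1.5-fold (335 kept their side), 18 with the suffix block, 14 with the compared groups alone, 12 with upper quartile factors, 10 with DESeq2, 6 with limma-voom, 5 without a filter, 3 with the stricter filter and 2 with RLE, and in 253 leaving out 1 library (2889 kept their side). Calls were gained in 9 without a filter, 6 leaving out 1 library and 4 with DESeq2. The compared groups alone and upper quartile factors gained 3 each, the stricter filter 2, and RLE and the suffix block 1 each. Against a minimum of 1.5-fold, calls in B cells were 2836 (MSA2 against Control), 64 (combination against Control) and 2614 (combination against MSA2), in BMDC 772 (MSA2) and 427 (combination against Control), and for the cell type difference 2918 and 2002. The combination against Control in B cells gave 359 without a filter, 385 with DESeq2, 260 with the title suffix as a block, and 91 to 169 leaving out 1 library. In BMDC the combination against Control gave 843 to 1658 leaving out 1 library. There the combination against MSA2 gave 561 without a filter, 154 with DESeq2, 3 with limma-voom, 13 with the compared groups alone, and 0 to 99 leaving out 1 library, and the count of opposite changes was 0 to 96. Of the gene list tests 0 held with an estimated correlation. The cause was not tested, except that a minimum of 1.5-fold makes a test stricter by construction. Leaving out a library lowered some counts and raised others, such as that of the BMDC combination against MSA2, from 0 to 99.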

Other observations

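The gene families here were chosen after their values were seen, and no test of an explanation was run on them. Interferon alpha genes, which share reads, rose in both cell types: 7 of 7 with MSA2 and 6 of 7 with the combination in B cells, 12 of 12 and 12 of 12 in BMDC. PYHIN genes, sensors of DNA, rose in BMDC (12 of 12 and 10 of 12), and in B cells 7 of 12 rose and 2 fell with MSA2, alongside the other-cell markers, and 0 of 12 rose with the combination. Schlafen genes, which restrict viruses, rose in BMDC (7 of 7 and 5 of 7) and in B cells with MSA2 (5 of 8, in the same libraries), against 0 of 8 with the combination. Guanylate-binding proteins, which attack microbes inside cells, rose in B cells with MSA2 (9 of 11), alongside the other-cell markers, and 1 of 11 did with the combination, while in BMDC 5 of 10 rose and 1 fell with MSA2. TNF ligand genes rose in BMDC (11 of 15, with 1 that fell, and 8 of 15) and in B cells with MSA2 (13 of 16, alongside the other-cell markers), against 2 of 16 with the combination.

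The tables also count the reporter eGFP, at 74.2 ± 6.24 CPM of the unscaled total in Control B cells and 58.5 ± 0.968 CPM in Control BMDC (n = 3 each), while Cre, mCherry and tdTomato had 0 counts.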
